A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

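Total RNA from Saccharomyces cerevisiae was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample and 8 arrays in all. Per the labels, exponentially growing cells of 3 strains were sampled, the wild type and the strains labelled rnt1d and rnt1ts, each at 26 C and at 37 C. What these strain labels stand for is not given in the sources used here. Wild type and rnt1d at 26 C have 2 arrays each, which the labels call biological replicates. The remaining 4 groups (rnt1ts at 26 C and each strain at 37 C) have 1 array each. The growth protocol names complete medium with or without leucine, the design text names rich medium, and neither says which array had which.

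The deposited values are linear intensity signals per probe set, made by the authors with MAS5, per the submitters' processing notes. A version, a target intensity for scaling and an annotation release are not given in the sources used here. MAS5 gives no negative signals, so a transcript at background has a small positive value whose ratio to another value has little meaning. The deposited arrays were not on a common scale. Their means after trimming 2% at each end ran from 103 on rnt1d at 26 C replicate 2 to 195 on rnt1d at 26 C replicate 1.

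The design fixed before the data were examined took the deposited scaling as it stood, on the assumption that MAS5 had scaled the arrays to 1 target. The values showed otherwise. Quantile normalization between arrays, which had been listed beforehand as an alternative, was therefore made the main setting, and the deposited scale and a median scaling became alternatives. This change was made after the values had been seen, and both counts are given where it matters. All 9335 probe sets, the 60 controls included, entered the normalization, so that the background bound has the same scale as the genes. With the controls left out of it, 527 probe sets in place of 509 passed the test of rnt1d against wild type at 26 C, and these included all 509.

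Values were tested as log2(signal + 16), and each fold change is on that scale, which understates the change of dim transcripts. The 9275 probe sets that are not controls were tested. Of these, 6504 name 1 gene, 328 name several and 2443 are unnamed in the platform annotation used here. The 6504 probe sets cover 5656 genes, all 6504 matched a gene in a table of assembly R64, and no symbol had to be updated. A gene with several probe sets was represented by the one with the highest mean over the 8 arrays. A probe set was taken as not above background on an array when its signal was at or under the highest of 19 control probe sets for non-yeast transcripts there. That bound ran from 3.48 to 10.7 after normalization. Where a group was not above background, the fold is given as at least N-fold, the brighter group's mean against the bound or the dim probe set's own signal, whichever is higher, as means of log2 values.

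The main model was a limma fit of 6 group means over the 8 arrays, with moderated variances that follow the mean signal, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Only the 2 groups with 2 arrays contribute to its spread, with 2 residual degrees of freedom, and a lone array is assumed to vary like them. It gave rnt1d against wild type at 26 C, rnt1ts against wild type at 26 C, the change of the rnt1d effect between temperatures, and the difference between rnt1ts and wild type in their temperature effects. The comparison of 37 C with 26 C came from a limma fit with strain and temperature as additive terms. At 37 C alone there is 1 array per strain, and differences there were counted without a test. The number of arrays limits the precision of every value.

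Members of 24 gene lists, fixed before the data were examined, were counted by their call over all probe sets and after adjustment over the list alone. The lists covered snoRNAs of polycistronic transcripts, intron-encoded snoRNAs and their host genes, other box C/D snoRNAs, box H/ACA snoRNAs, snRNAs and other stable RNAs, mRNAs reported as Rnt1 substrates, the iron regulon, hexose transporters, cell wall integrity, heat shock, general stress, cytosolic ribosomal proteins, snoRNP and assembly proteins, nuclear RNA processing, Gcn4 targets, auxotrophic markers, a-specific, alpha-specific and haploid-specific genes, cell cycle, respiratory chain, the phosphate regulon and DNA damage. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation and with fry, which does not compare a list with other genes.

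The genes named were taken from sets that a rule fixed beforehand: RNT1, the 15 highest and 15 lowest of the called probe sets with 1 gene in each tested comparison (5 by smallest p where under 5 passed), up to 4 called members of each list or 3 members by smallest p if none was called, and the 10 highest and 10 lowest in single-array differences among probe sets above the median signal. A gene named outside this rule is said to have been chosen after its values were seen.

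Alternatives fixed beforehand were pseudocounts of 1 and 64, the deposited scale, median scaling, filters at the 25th and 50th percentile of the mean signal, variances without a trend, leaving out each array, smaller sets of arrays and the replicate number as a block. Replicate numbers 1 and 2 were shared by wild type and rnt1d at 26 C, but with 2 pairs they were not shown to pair the samples. Hybridisation controls were present on wild type at 26 C replicate 2 (mean signal 232) and rnt1d at 26 C replicate 2 (208) and at or under 8.64 elsewhere. These arrays were treated as a batch, which coincides with replicate number 2 at 26 C. That batch, the fits without the 2 arrays whose RNT1 signal goes against their labels, and the tests of those labels were added after the data had been seen.

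The fit was tested on simulated data for rnt1d against wild type over 9275 probe sets. It recovered 55 of 100 simulated 2-fold changes and 94 of 100 simulated 4-fold changes with 7 false calls, and made 0 calls when no change was simulated. The changes were placed only in probe sets above the median signal, with independent noise and no batch. These figures therefore do not cover dim transcripts or the hybridisation batch. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.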

Results

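Transcript levels were measured on 8 Affymetrix yeast arrays from cells of 3 strains, labelled wild type, rnt1d and rnt1ts, at 26 C and 37 C. RNT1 encodes the yeast RNase III, a nuclear endonuclease that cuts stem-loops in precursors of ribosomal RNA, snRNAs and many snoRNAs. The series title places the study around snoRNA processing signals that depend on this enzyme. Wild type and rnt1d at 26 C had 2 arrays each and the 4 remaining groups 1 each, so single arrays carry no replicate check. The median deposited signal per array ran from 31.1 to 70.1. Arrays measure steady-state RNA, and a probe set for a snoRNA can read the mature RNA or an unprocessed precursor.

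The RNT1 transcript itself was examined first. Its normalised signal was 165 ± 22.7 (SD, n = 2) in wild type at 26 C and 269 on the wild type array at 37 C. In rnt1d at 26 C it was 1.67 ± 0.511 (SD, n = 2), not above background and at least 20.6-fold lower than in wild type (limma, adjusted p = 0.000939). In rnt1ts at 26 C it was 39.8, a log2 change of -1.69 (SE 0.23, adjusted p = 0.0485). At 37 C the signals went against the labels: RNT1 was at 71.4, above background, on the array labelled rnt1d, and at 1.26, not above background, on the array labelled rnt1ts. Both are called by their labels below, and no array was moved to another group. Where the probe set lies relative to any deletion is not given in the sources used here.

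**Figure D1:**
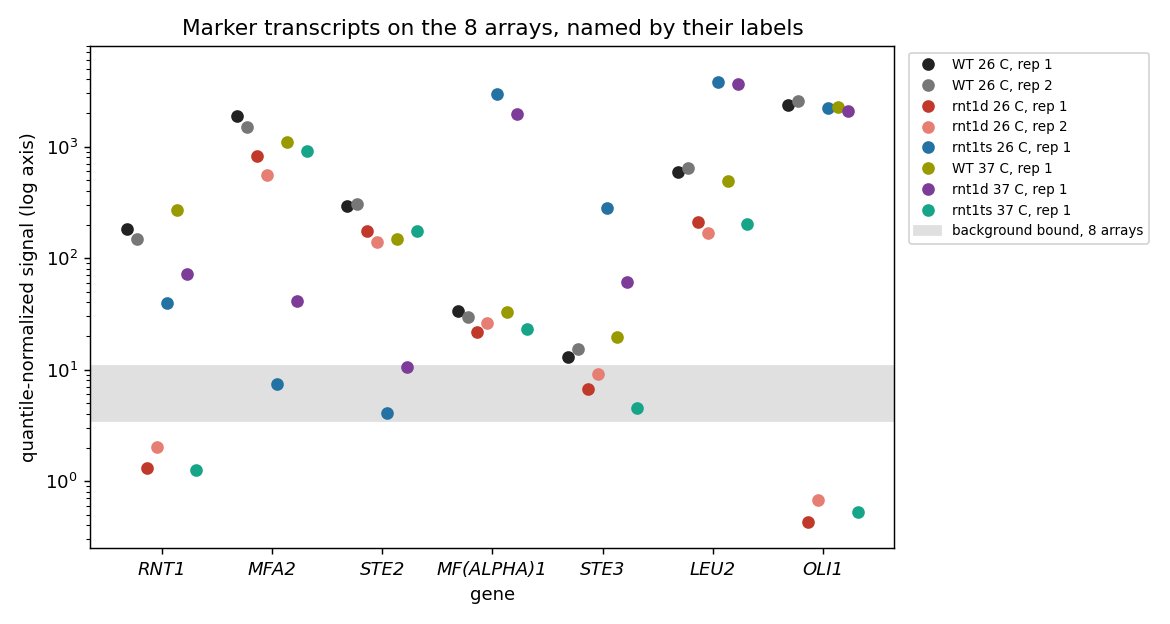
Normalised signal of RNT1 and other marker transcripts on each of the 8 arrays, on a log axis, with the arrays named by their labels. RNT1 was at 1.26 on the array labelled rnt1ts at 37 C and at 71.4 on the array labelled rnt1d at 37 C.

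In rnt1d at 26 C many of the largest rises were in small nucleolar RNAs. Of the 17 measured snoRNAs of polycistronic transcripts, box C/D guides of rRNA methylation that are cut apart from a shared precursor, 16 rose and 0 fell, both over all probe sets and adjusted over the list alone. SNR55 rose from 46.1 ± 16.8 to 2701 ± 302 (SD, n = 2 each), a log2 change of 5.47 (SE 0.23, adjusted p = 0.00029). SNR74, above background on 1 of 2 wild type arrays, rose to a signal of 679. SNR41 rose 25.6-fold, SNR73 23.2-fold, SNR70 20.1-fold, SNR57 18.7-fold, SNR51 14.2-fold, SNR76 10.5-fold and SNR72 10.4-fold. The median log2 change of the list was 3.38 (camera, adjusted p = 1.03e-25), and adjusted p = 0.192 with an estimated correlation. That estimated correlation was 0.0063, under the preset 0.01, so correlation among the members does not account for the higher p. On the single arrays the list's median lay 3.53 and 3.20 log2 units above the wild type mean in rnt1d replicates 1 and 2.

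Other snoRNA classes did not all follow. Of 20 further box C/D snoRNAs with their own promoter, 9 rose and 1 fell (12 and 3 adjusted over the list alone), with a median of 0.75 (adjusted p = 8.64e-07, and adjusted p = 0.206 with an estimated correlation). SNR71 rose 21.6-fold, SNR50 9.65-fold and SNR48 8.87-fold, and SNR64, not above background in wild type, was at least 20.2-fold higher. Among 16 box H/ACA snoRNAs, guides of pseudouridylation, 0 rose and 1 fell (0 and 4 adjusted over the list alone). SNR11 fell by 0.94 log2 units (SE 0.18, adjusted p = 0.043). The median of that list was -0.19 (adjusted p = 0.0271, and adjusted p = 0.535 with an estimated correlation), and its call was lost on the deposited scale, with median scaling, with the 25th and 50th percentile filters, with fry, and without wild type replicate 2 or rnt1d replicate 1 at 26 C. None of 4 intron-encoded snoRNAs was called (0 higher and 1 lower adjusted over the list alone), with log2 changes of -1.21 for SNR44, -0.71 for SNR38 and 0.27 for SNR39, and a list median of -0.42 (adjusted p = 0.251). Without rnt1d replicate 1 at 26 C that list was called, at -0.75 (adjusted p = 0.0129).

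Of 6 spliceosomal snRNAs and other stable RNAs, 3 rose and 0 fell (5 and 1 adjusted over the list alone). SNR19, the U1 RNA, rose 10.1-fold and SNR14, the U4 RNA, rose 3.71-fold. SNR7-L, the long form of U5, was at least 3.61-fold higher. The list's median was 0.85 (adjusted p = 0.00183, and adjusted p = 0.208 with an estimated correlation). A probe set for 25S rRNA, RDN25-1, had the highest change of all, from 26.3 ± 9.92 to 4789 ± 396 (SD, n = 2 each), a log2 change of 6.85 (SE 0.21, adjusted p = 0.000151). The second RDN25-1 probe set had a log2 change of -0.22 and was not called. The brightest probe set of RDN37-1, another rRNA gene, chosen after its values were seen, did not rise. Its signals were 1077 and 1180 in wild type and 578 and 835 in rnt1d. As rRNA probe sets disagreed, the rise does not show that the level of 25S rRNA as a whole rose.

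**Figure D2:**
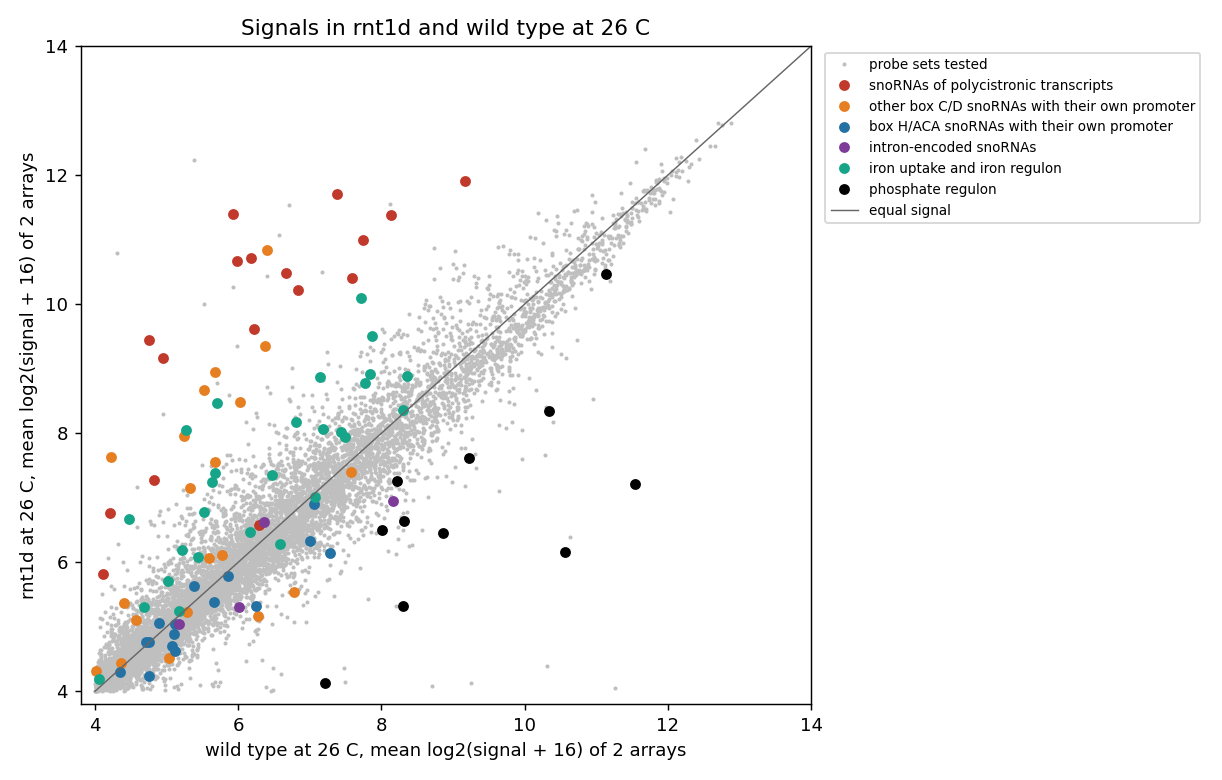
Mean log2(signal + 16) of the 2 rnt1d arrays against that of the 2 wild type arrays at 26 C for the 9275 probe sets tested, with 6 gene lists in colour and the line of equal signal. The snoRNAs of polycistronic transcripts (median 3.38) lie above the line and the phosphate regulon (median -2.0) below it.

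Iron regulon transcripts were higher in rnt1d at 26 C. Of 27 measured genes, 10 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.89 (adjusted p = 2.43e-12, and adjusted p = 0.206 with an estimated correlation). FIT2 and FIT3, cell wall mannoproteins that retain siderophores, rose 6.86-fold and 5.20-fold. SIT1, a siderophore transporter, rose from 36.3 ± 5.25 to 338 ± 46.0 (SD, n = 2 each), and TIS11, which promotes decay of mRNAs for iron-using proteins, rose from 6.35 to 89.5, its wild type signal being above background on 1 of 2 arrays. OLI1, ATP6 and COX1, described below, were not above background on the same arrays. Of 14 mRNAs reported as Rnt1 substrates, 3 rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.000265, and adjusted p = 0.206 with an estimated correlation). These were FIT2 and ARN2 (3.26-fold), and RPS22B (1.88-fold, 2 of 3 probe sets called), which encodes a ribosomal protein and hosts a snoRNA in an intron. FIT2 and ARN2 are also on the iron list and RPS22B on the list of host genes. The call of the substrate list is therefore not separate from those lists. Among the 8 host genes of intronic snoRNAs, RPS22B rose and RPL7B fell by 2.36 log2 units (1 and 2 adjusted over the list alone), and the list was not called at a median of -0.29 (adjusted p = 0.104), although it was called on the deposited scale, with median scaling, with the replicate block (adjusted p = 0.0427), with the batch term (adjusted p = 0.0429) and without rnt1d replicate 1 at 26 C (median -0.63, adjusted p = 0.00601).

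Phosphate regulon and respiratory transcripts were lower. Of 11 phosphate genes, 8 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -2.0 (adjusted p = 3.01e-10, and adjusted p = 0.235 with an estimated correlation). PHO5, a secreted acid phosphatase, fell from 1495 ± 15.7 to 57.0 ± 19.1 (SD, n = 2 each). PHO84, the high-affinity phosphate transporter, fell by 4.33 log2 units (SE 0.83, adjusted p = 0.0445), with signals of 2950 ± 12.7 and 207 ± 236. SPL2 fell by 2.99 and VTC3 fell by 2.40 log2 units, and PHM6 was at least 16.5-fold lower. GIT1, a glycerophosphoinositol transporter outside the list, fell by 2.88. Of 28 respiratory chain genes, 10 fell and 0 rose (17 and 2 adjusted over the list alone), with a median of -0.70 (adjusted p = 1.62e-07, and adjusted p = 0.208 with an estimated correlation). The nuclear genes COX4, ATP3, SDH1 and COR1 of that list had log2 changes of -1.86, -1.30, -1.18 and -1.17.

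OLI1, COX1 and ATP6, which are encoded in the mitochondrial genome, were not above background in rnt1d at 26 C. OLI1 was at 2448 ± 133 (SD, n = 2) in wild type and at least 307-fold lower in rnt1d, although a second OLI1 probe set had a log2 change of 0.07 and was not called. COX1 was at least 157-fold lower, with all 3 of its probe sets called lower, and ATP6 at least 74.2-fold lower (limma, adjusted p = 0.000151 for both COX1 and ATP6). Of 5 other mitochondrial genes, chosen after their values were seen, COX3, COB and ATP8 fell (adjusted p = 0.00964, 0.00855 and 0.0329), and COX2 and VAR1, at or near background in wild type too, were not called (adjusted p = 0.386 and 0.433). The same 3 genes were not above background on the array labelled rnt1ts at 37 C, and OLI1 was at 2100 on the array labelled rnt1d at 37 C.

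Some genes of amino acid synthesis and some a-specific genes also fell. Of 26 Gcn4 targets and leucine synthesis genes, 7 fell and 0 rose (15 and 2 adjusted over the list alone), with a median of -0.55 (adjusted p = 7.17e-06, and adjusted p = 0.211 with an estimated correlation). The log2 changes were -1.99 for ARG1, -1.65 for ARG4, -1.63 for LEU2 (1 of 3 probe sets called, -1.63 to -1.20) and -1.28 for BAT1. Which arrays came from medium without leucine is not stated. LEU2 fell and TRP1 rose by 1.26 among 6 auxotrophic marker genes (2 higher and 3 lower adjusted over the list alone), and that list was not called (median -0.081, 0.15 on the deposited scale, adjusted p = 0.903). Of 7 a-specific genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.87 (adjusted p = 0.000346, and adjusted p = 0.206 with an estimated correlation). Their log2 changes were -1.65 for MFA1, -1.57 for BAR1 and -1.28 for MFA2. None of 4 alpha-specific genes was called (1 higher and 0 lower adjusted over the list alone), with log2 changes of 0.91 for SAG1, -0.44 for MF(ALPHA)2 and -0.33 for STE3 (0.15 in the additive model) and a median of -0.30 (adjusted p = 0.478), or 0.33 with the 50th percentile filter. Of 9 haploid-specific genes, FAR1 and HO fell, with log2 changes of -1.59 and -1.57 (0 higher and 6 lower adjusted over the list alone), with a median of -0.56 (adjusted p = 0.00349, and adjusted p = 0.208 with an estimated correlation).

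Cell wall and heat shock genes rose in part. Of 24 cell wall integrity genes, 6 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.37 (adjusted p = 7.17e-06, and adjusted p = 0.206 with an estimated correlation). PIR3 rose 4.81-fold, GSC2 4.06-fold, YPS3 3.21-fold and CRH1 2.86-fold. Of 7 GSC2 probe sets 2 were called, with log2 changes over all 7 from 0.25 to 2.02. Of 27 heat shock genes, HSP30, SSE2 and FES1 rose by 1.83, 1.23 and 0.92 log2 units (9 higher and 0 lower adjusted over the list alone), with a median of 0.46 (adjusted p = 0.000133, and adjusted p = 0.267 with an estimated correlation). That call was lost with median scaling (adjusted p = 0.118) and with fry. Of 22 hexose transporter and glucose repression genes, MIG3 and MTH1, which encode transcriptional regulators, rose by 1.36 and 1.18, and HXT1 fell by 1.35 (6 higher and 2 lower adjusted over the list alone). The median of 0.22 was called (adjusted p = 0.0202, and adjusted p = 0.535 with an estimated correlation), and not with median scaling, on the deposited scale, with the 50th percentile filter, with fry or without rnt1d replicate 2 at 26 C.

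Genes for ribosomes shifted down slightly. Of 77 cytosolic ribosomal protein genes, RPL9B and RPL22B fell (-1.64 and -1.56 log2 units) and 0 rose (2 lower and 0 higher adjusted over the list alone), with a median of -0.17 (adjusted p = 0.000419, and adjusted p = 0.206 with an estimated correlation). Of 30 genes for snoRNP proteins and ribosome assembly, NUG1 rose by 0.80 and 0 fell (0 and 0 adjusted over the list alone), against a median of -0.46 for the list (adjusted p = 0.000305, and adjusted p = 0.535 with an estimated correlation). That median was -0.19 on rnt1d replicate 1 and -0.77 on replicate 2, and the call was lost with fry. Medians of other called lists differed between the 2 arrays too, among them the phosphate regulon (-2.47 and -1.81), polycistronic snoRNAs (3.53 and 3.20) and snRNAs (0.75 and 0.95). Further examples were other box C/D snoRNAs (0.57 and 1.04), box H/ACA snoRNAs (-0.34 and -0.16), hexose transporters (0.14 and 0.30) and heat shock (0.29 and 0.48). The lists not called were nuclear RNA processing (27 genes, 0 called, median -0.13, adjusted p = 0.207), general stress (24 genes, SPI1 higher, median 0.18, adjusted p = 0.104), cell cycle (23 genes, PCL1 higher by 1.56, median -0.078, adjusted p = 0.531) and DNA damage (8 genes, RNR1 higher by 0.94, adjusted p = 0.903). Adjusted over the list alone they had 0 higher and 0 lower, 3 and 3, 1 and 3, and 1 and 1. In the first of these the smallest p belonged to LSM2 (-0.59), PAP2 (-0.54) and NAB2 (0.50). Without rnt1d replicate 1 at 26 C the general stress list was called, at a median of 0.33 (adjusted p = 0.00189). On the deposited scale the medians of nuclear RNA processing, cell cycle and DNA damage were 0.13, 0.16 and 0.23. The DNA damage list had a median of -0.048 and a mean of 0.015, and its test pointed up.

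**Figure D3:**
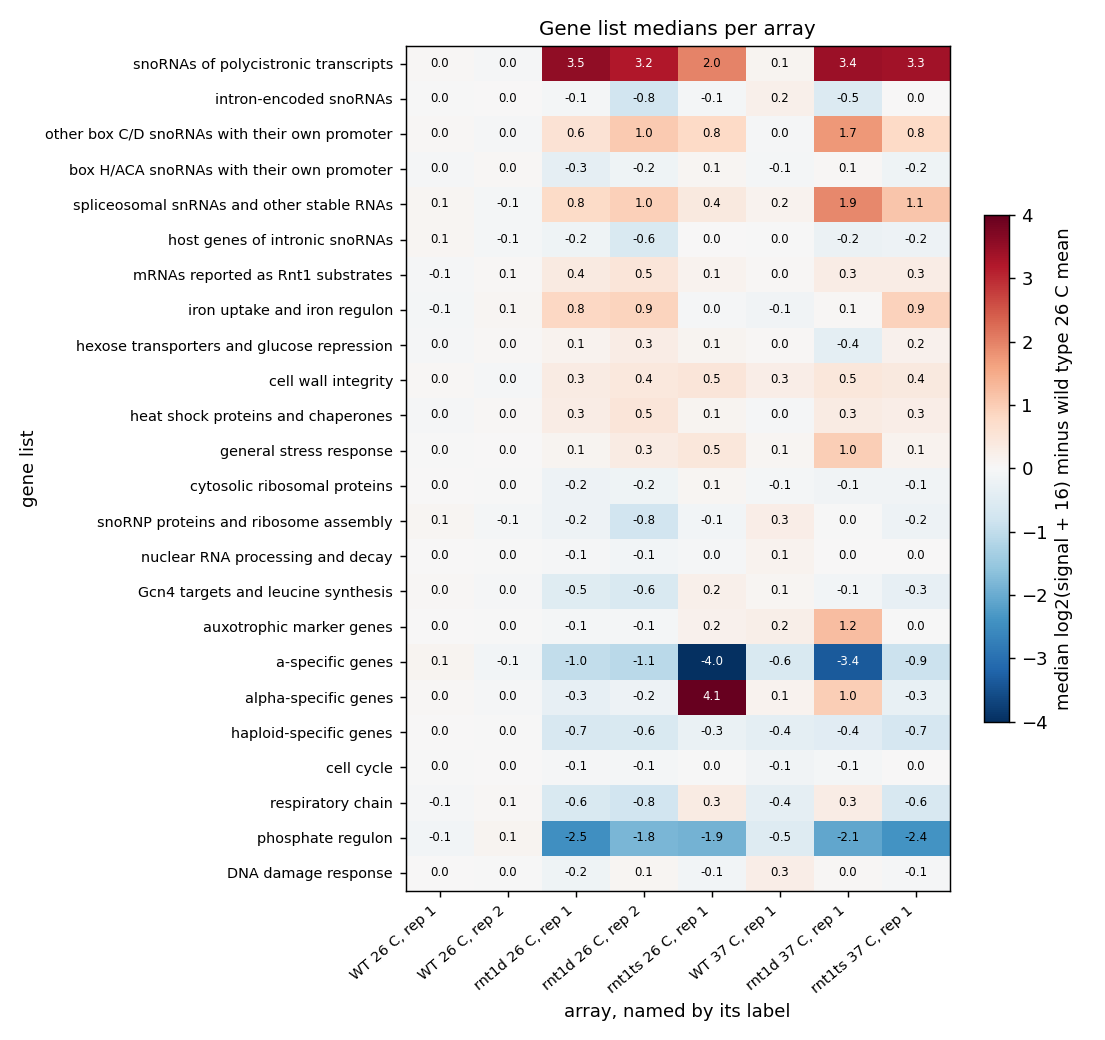
Median log2(signal + 16) of each of the 24 gene lists on each of the 8 arrays, less the mean of the 2 wild type arrays at 26 C, with the arrays named by their labels. The snoRNAs of polycistronic transcripts were at 3.53 and 3.20 and the phosphate regulon at -2.47 and -1.81 on the rnt1d arrays at 26 C.

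Over all probe sets, 509 of 9275 differed between rnt1d and wild type at 26 C, 328 higher and 181 lower (limma, adjusted p under 0.05), covering 249 and 151 genes, and 370 of them differed at least 2-fold. Beyond the genes above, SPI1, a cell wall protein, and DPI8 rose by 3.37 and 3.32 log2 units. The log2 changes of YNL134C, MET17, HSP31 and GTT2 were -2.54, -2.43, -2.21 and -2.17. All 509 had the same sign within replicate number 1 and within number 2, where 500 and 680 of all probe sets differed at least 2-fold. The calls were made on these same arrays, so the shared sign is no separate support for them. With the hybridisation batch as a term, 1425 were called, 784 higher and 641 lower, and they included all 509. With median scaling 540 were called, 216 higher and 324 lower, of which 389 were shared. On the deposited scale 100 were called, 69 higher and 31 lower, of which 88 were shared. The median log2 change of all probe sets was -0.029 after quantile normalization, 0.12 on the deposited scale and -0.081 with median scaling. Leaving out an array left 41 calls without wild type replicate 1, 33 without wild type replicate 2, 231 without rnt1d replicate 1 and 103 without rnt1d replicate 2 at 26 C. Of the 30 genes named by rank, 18 were called whichever array was left out, and 29, all but GTT2, were called under both other scalings.

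The strain labelled rnt1ts was compared with wild type at 26 C on 1 array. Here too polycistronic snoRNAs were higher, 12 of 17, as were 7 of 20 other box C/D snoRNAs, while 0 of 16 box H/ACA snoRNAs and 0 of 27 iron regulon genes were called. SNR71 rose 12.6-fold, SNR73 12.0-fold, SNR70 7.17-fold, SNR52 7.05-fold, SNR51 6.98-fold and SNR57 6.30-fold, and SNR74 rose to a signal of 168. The largest changes were in mating-type genes. All 4 alpha-specific genes rose: MF(ALPHA)1 by 5.98 log2 units (SE 0.21, adjusted p = 0.00169), MF(ALPHA)2 by 4.96, STE3 by 3.30 and SAG1 by 3.22. AFB1, the a-factor barrier gene, rose 18.1-fold. Of 7 a-specific genes, 5 fell. MFA2 was at least 165-fold lower, MFA1 at least 87.4-fold, BAR1 at least 45.3-fold, STE2 at least 29.4-fold and AGA2 at least 14.5-fold, and HMRA1 was at least 11.6-fold lower. Not all probe sets of these genes were called: the second for MFA1 had a log2 change of -1.93, and of 3 for HMRA1 only 1 was called, with values from -2.90 to -0.59. The markers of mating type therefore differed between the strains compared, and every other difference between rnt1ts and wild type was measured beside that one.

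LEU2 rose 6.04-fold (2 of 3 probe sets called), INO1, the inositol synthesis enzyme, 21.9-fold, and PIR3 9.25-fold in rnt1ts. Of 11 phosphate genes, 4 fell, with log2 changes of -2.91 for PHO5 and -1.88 for VTC3, and PHM6 at least 12.9-fold lower. Further log2 changes were -2.98 for GIT1, -2.72 for GTT2, -2.28 for AAD4 (1 of 2 probe sets called), -2.19 for PTR2 and -1.95 for ATR1. COX1 probe sets disagreed, with log2 changes of -2.58, 1.98 and 2.35, each called. In all, 73 of 9275 probe sets were called, 54 higher and 19 lower (limma, 831 at an unadjusted p under 0.05). No call was left without wild type replicate 1 or replicate 2 at 26 C, but then only the rnt1d pair gives the spread. That loss therefore does not show that each difference rests on both of those arrays. Of the 30 genes named by rank, 21 were called under both other scalings, and AGA2, GIT1, HMRA1, GTT2, COX1, AAD4, PTR2, ATR1 and VTC3 were not.

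At 37 C each strain had 1 array, and differences there were counted without a test. Between the array labelled rnt1d and wild type, 545 probe sets differed at least 2-fold, 239 higher and 306 lower (199 and 344 on the deposited scale). Between the array labelled rnt1ts and wild type 641 did, 333 higher and 308 lower (235 and 471 on the deposited scale), and between the 2 labelled mutant arrays 554 did. These counts depend on the pseudocount, being 1391, 1767 and 1580 with 1 and 351, 307 and 264 with 64. Replicates at 26 C differed as much for 83 probe sets in wild type and 145 in rnt1d. Polycistronic snoRNAs were high on both mutant arrays: SNR74 was 32.0-fold and SNR73 28.4-fold above wild type on the array labelled rnt1d, and SNR55 was 34.6-fold and SNR41 22.9-fold above it on the array labelled rnt1ts. The array labelled rnt1d had MF(ALPHA)1 40.3-fold higher and MFA1 and MFA2 25.2-fold and 19.7-fold lower than wild type, while MF(ALPHA)2 and SAG1, at 13.4 and 69.7, were near their wild type signals of 17.6 and 61.1. The array labelled rnt1ts had OLI1, ATP6 and COX1 not above background, FET3, an iron oxidase, 17.4-fold higher and PHO84 53.2-fold lower than wild type. FET3 was at 763 there and at 28.7 on the wild type array at 37 C, against 149 and 318 in wild type at 26 C. Its fold therefore rests in part on that wild type array. ANB1 and TIR1, known as genes of low-oxygen growth, stood apart on the wild type array at 37 C, at 1396 and 5012 against 29.5 to 87.2 and 156 to 351 on the other 7 arrays. Their differences from it on both mutant arrays therefore rest on that 1 array. Both labels go against the RNT1 signal. Directions seen on both arrays, such as those of SNR74 and SNR73, would stand if the 2 labels were exchanged, and those seen on 1 array alone cannot be assigned to a strain.

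Agreement with the differences at 26 C was counted on disjoint arrays. Of the 509 probe sets called in rnt1d at 26 C, 406 (79.8%, exact 95% interval 76.0 to 83.2) had the same sign on the array labelled rnt1d at 37 C against wild type. On the array labelled rnt1ts 497 (97.6%, 95.9 to 98.8) did. Of the 545 probe sets at least 2-fold apart on the array labelled rnt1d, 510 (93.6%, 91.2 to 95.5) had the same sign in rnt1ts at 26 C. Probe sets are not independent, so the intervals cover counting error only.

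Whether the strain effects changed with temperature was tested in the same model, and here the 2 labelled mutant arrays enter directly. For rnt1d, 6 probe sets were called, all higher (889 at an unadjusted p under 0.05), although the split was 62 higher and 62 lower with the batch term and 30 and 17 with the 25th percentile filter. Among them MF(ALPHA)1 was higher by 5.59 log2 units (SE 0.29, adjusted p = 0.00899) and LEU2 by 4.46. OLI1 (adjusted p = 0.00191) and ATP6 (adjusted p = 0.0104) were called too, against signals not above background in rnt1d at 26 C, so their log2 values depend on the pseudocount. A second OLI1 probe set was not called, and of 3 for LEU2 only 1 was called. In the 6-group model no probe set was called lower, and the smallest p values there belonged to ANB1 (-4.25), TIR1 (-4.78), SIT1 (-2.96), DAN1 (-2.50) and YER187W (-2.19). Those of ANB1 and TIR1 rest on the wild type array at 37 C. For rnt1ts against wild type, 23 were called, 5 higher and 18 lower (995 at an unadjusted p under 0.05), although the split was 50 higher and 60 lower with the batch term and 39 and 38 with the 50th percentile filter. RDN25-1 was higher by 6.64, with 1 of 2 probe sets called. MFA2, STE2 and BAR1 were called higher from signals not above background in rnt1ts at 26 C, and OLI1 and STE3 lower to signals not above background on the array labelled rnt1ts at 37 C, so their log2 values depend on the pseudocount. Other log2 values below 0 were -6.30 for MF(ALPHA)1, -5.38 for INO1, -3.86 for ARG1, -3.64 for ARG3, -3.60 for MET13, -3.10 for ARG4 and -3.03 for ARG7. Both counts were 0 without either wild type array at 26 C. Without rnt1d replicate 1 or 2 at 26 C the first was 1, and without rnt1d replicate 1 the second was 15. Without rnt1ts at 26 C the first was 11. Apart from those of ANB1 and TIR1, these directions rest on arrays whose RNT1 signal goes against their labels.

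Over the 3 strains together, 37 C against 26 C gave 0 called probe sets (limma, smallest adjusted p = 0.39), with 884 at an unadjusted p under 0.05. The strain term of this model takes the 2 mutant arrays at 37 C by their labels, which their RNT1 signals go against. If the labels were exchanged, strain differences would add to the spread. The count of 0 therefore does not show that temperature had no effect. The heat shock list was not called, at a median of -0.047 (camera, adjusted p = 0.94). The smallest p values belonged to YOR338W (2.16), SHH3 (0.93), NCA3 (1.35), GDH3 (1.57) and MCH5 (1.10) among log2 changes above 0, and LYS9 (-0.83), HO (-1.42), ARO10 (-1.08), IBA57 (-0.55) and DAD2 (-0.68) among those below. By list, camera called 9 of 24, and with an estimated correlation 0. Medians were 0.49 for polycistronic snoRNAs (adjusted p = 7.74e-05, and adjusted p = 0.672 with an estimated correlation), 0.14 for other box C/D snoRNAs (0.00176 and 0.362) and 0.45 for snRNAs (0.00793 and 0.362). They were 0.21 for snoRNP and assembly genes (0.000229 and 0.713), 0.059 for nuclear RNA processing (0.0361 and 0.546) and 0.14 for cell wall genes (0.0115 and 0.546), the last being -0.045 with median scaling. They were -0.28 for phosphate genes (0.0119 and 0.672), -0.21 for haploid-specific genes (0.0457 and 0.546) and -0.049 for ribosomal proteins (0.0438 and 0.927). Each of the 9 calls was also lost under at least 1 other alternative. Leaving out wild type at 37 C ended those of cell wall (0.055, adjusted p = 0.317), nuclear RNA processing (0.048, 0.12), phosphate (-0.19, 0.198), haploid-specific genes (-0.17, 0.188) and ribosomal proteins (-0.039, 0.188). Leaving out rnt1ts at 26 C ended those of phosphate (-0.28, 0.124), haploid-specific genes (-0.11, 0.163) and ribosomal proteins (-0.0060, 0.886), and leaving out the array labelled rnt1ts at 37 C ended the same 3. Leaving out the array labelled rnt1d at 37 C ended those of nuclear RNA processing (0.063, 0.105), other box C/D snoRNAs (0.12, 0.101) and snoRNP and assembly genes (0.072, 0.062). Nuclear RNA processing was also not called without wild type replicate 2 or rnt1d replicate 2 at 26 C, with pseudocount 1, on the deposited scale, with median scaling or with the 25th percentile filter. Haploid-specific genes and ribosomal proteins were not called with pseudocount 1, with either filter or without wild type replicate 1 at 26 C, and haploid-specific genes not without wild type replicate 2. Cell wall was not called on the deposited scale or with median scaling, snoRNP and assembly genes not with median scaling, and snRNAs not with the 50th percentile filter. The polycistronic list also lost its call without the rnt1ts array at 26 C, with a median of -0.058. It lost it too without the array labelled rnt1ts at 37 C, with a median of -0.058. Relative to wild type at 26 C, this list's median was 0.12 on the wild type array at 37 C. It was 3.53 and 3.20 in rnt1d at 26 C and 3.43 on the array labelled rnt1d at 37 C. The larger difference was between the arrays labelled rnt1ts, 1.98 at 26 C and 3.35 at 37 C, so it may reflect the labels rather than temperature. Without both labelled mutant arrays at 37 C, 6 lists were called, but 5 of the 9 above lost the call: polycistronic snoRNAs (median 0.12, adjusted p = 0.0933), snRNAs (0.15, 0.119), other box C/D snoRNAs (-0.037, 0.367), nuclear RNA processing (0.14, 0.0933) and ribosomal proteins (-0.078, 0.099). Adjusted over the list alone, 2 polycistronic snoRNAs, 2 other box C/D snoRNAs and 2 snRNAs were higher and 1 haploid-specific gene was lower, with 0 in the other 5 lists called.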

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

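All tests of explanations in this part were chosen after the results had been seen, and so was the comparison of array labels.

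The first pattern is that the 2 mutant arrays at 37 C carry several of each other's markers, picked up because effects differed between temperatures in 6 probe sets for rnt1d and 23 for rnt1ts. A temperature response shared by the strains is argued against over 461 probe sets at least 2-fold apart between rnt1d and rnt1ts at 26 C (markers left out). Their median change towards rnt1ts was -0.083 in wild type, 0.85 on the array labelled rnt1d and -1.26 on the array labelled rnt1ts. The probe sets were chosen on the 26 C arrays from which the last 2 changes start. That choice alone can move both in these directions, by an amount not measured. Exchanged strain labels stay open. On the array labelled rnt1ts, 445 of the 461 (96.5%) and 12 of 12 markers lay nearer rnt1d. On the array labelled rnt1d, only 293 (63.6%) and 9 of 12 markers lay nearer rnt1ts. The exceptions were MF(ALPHA)2, STE3 and SAG1, so 1 of the 4 alpha-specific genes lay nearer. STE3 was at 60.5 there, against 281 in rnt1ts at 26 C and 6.71 and 9.10, near background, in rnt1d at 26 C. Which strain STE3 lay nearer therefore depends on the pseudocount. The share of probe sets was under the 75% set for that reading. It cannot decide against an exchange, since an exchanged array would also carry any change of rnt1ts with temperature. The array labelled rnt1ts may also hold cells grown at 26 C. Over 84 probe sets that changed in wild type at 37 C by a median of 1.42, it differed from rnt1d at 26 C by -0.088 (-0.14 and -0.017 against the 2 arrays). The array labelled rnt1d differed from rnt1ts at 26 C by 0.93. Over these 84 probe sets the median difference was 0.18 between replicates of either strain. Over all probe sets, the array labelled rnt1ts differed at least 2-fold in 25 from rnt1d replicate 1 at 26 C and in 103 from replicate 2. The rnt1d replicates at 26 C differed as much in 145 and the wild type replicates in 83. Both replicate pairs cross the hybridisation batch. An rnt1d strain that lacks the wild type response to 37 C would give the same values and remains an untested biological explanation.

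In the rnt1d difference between temperatures the called probe sets were OLI1 (7.12), MF(ALPHA)1 (5.59), ATP6 (5.20), 1 of the 4 ZRT1 probe sets (5.13), LEU2 (4.46) and 1 of the 3 COX1 probe sets (3.98), in log2 units. In the rnt1ts difference from wild type those above 0 were 1 RDN37-1 probe set (6.82), 1 of the 2 RDN25-1 probe sets (6.64), MFA2 (5.92), STE2 (4.18) and BAR1 (4.11). Those below 0 were OLI1 (-6.97), MF(ALPHA)1 (-6.30), ATP6 (-5.55), INO1 (-5.38), MF(ALPHA)2 (-5.20), AFB1 (-4.69), COX1 (-4.37 and -4.06), a probe set that names several genes (-4.26), STE3 (-4.09), ANB1 (-3.93), ARG1 (-3.86), LEU2 (-3.82), ARG3 (-3.64), MET13 (-3.60), ARG4 (-3.10), ARG7 (-3.03) and SAM2 (-2.82). Those that were not above background in a group of their contrast, so that the value depends on the pseudocount of 16, were OLI1, ATP6 and COX1 in both contrasts, and RDN37-1, MFA2, STE2, BAR1 and STE3 in that of rnt1ts. The brightest RDN37-1 probe set was not called. It was at 1041 in rnt1ts at 26 C and 759 on the array labelled rnt1ts at 37 C, and at 1077, 1180 and 960 in wild type. All values of the 2 contrasts involve an array whose RNT1 signal goes against its label. That of ANB1, however, comes from the wild type array at 37 C (1396), with 63.3 in rnt1ts at 26 C and 56.8 on the array labelled rnt1ts at 37 C.

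A control probe set for 25S rRNA, outside the tested probe sets, had deposited signals of 6027 and 3345 on the rnt1d arrays at 26 C, 897 on the array labelled rnt1d at 37 C and 5387 on the array labelled rnt1ts at 37 C. The wild type arrays were at 28.2, 14.9 and 31.6 and rnt1ts at 26 C at 41.6.

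The second pattern is the rise of iron regulon transcripts in rnt1d at 26 C. Scaling between arrays is argued against: the median was 0.89 after quantile normalization, 1.16 on the deposited scale and 0.85 with median scaling, where the same list's median differed between replicates by at most 0.13, 0.82 and 0.17. A rise in log2 proportion to the polycistronic snoRNAs, as from loss of Rnt1 activity, was not seen on 2 arrays. The snoRNA and iron medians were 1.98 and -0.037 in rnt1ts at 26 C and 3.31 and 0.21 on the array labelled rnt1d at 37 C. The iron medians fell short of proportion by 0.56 and 0.65, more than the interquartile range of the list's members (0.46 and 0.50). That range is not the error of a single-array median. Both arrays had RNT1 above background (39.8 and 71.4) and high MF(ALPHA)1 (2988 and 1957) and LEU2 (3812 and 3630). They may be 1 strain rather than 2 separate tests, and they do not argue against loss of Rnt1 activity as such. A rise only beyond some loss of Rnt1 activity was not tested. Loss of mitochondrial transcripts cannot be told apart from loss of the RNT1 transcript. RNT1 and OLI1 were both above or both at background on 8 of 8 arrays. The iron median was 1.27 on the array labelled rnt1ts at 37 C, where both were at background. OLI1 was at 2224 in rnt1ts at 26 C and at 2100 on the array labelled rnt1d at 37 C. On these 2 arrays the snoRNA list rose with OLI1 present, and the iron medians were the -0.037 and 0.21 above. With 1 array each, and 1 label in doubt, this does not settle the cause.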

How the results depend on the processing

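The hybridisation batch and the fits without the 2 labelled mutant arrays at 37 C were added after the data had been seen. With 1 or 2 arrays per group and 2 residual degrees of freedom, counts of calls move far with the spread estimate, and dim transcripts are limited by background. Where no cause is named, the cause was not tested. Among genes named, 2244 values under alternatives kept direction and side of the threshold, 374 lost the call, 47 gained it and 3 changed sign. For lists these were 505, 85, 7 and 12. Every sign change was of a value not called under the alternative. Genes of lists outside rnt1d at 26 C and the 15 temperature lists not called were not followed one by one, a restriction set after a fuller run had shown many sign changes among such values near 0. Of those 15 lists, 14 changed the sign of their median under some alternative and 8 were called under some alternative.

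For rnt1d at 26 C (509 calls), the deposited scale gave 100, the 25th percentile filter 895, where fewer probe sets are tested, and the additive model on 6 arrays 297. The replicate block gave 1374 (760 higher, 614 lower, all 509 included), and the batch term, the same split of these 4 arrays, 1425. The 2 within-number differences correlated at 0.770 across probe sets and replicate deviations at 0.311, which with 2 pairs does not show pairing. Leaving out an array gave 33 (without wild type 26 C replicate 2) to 528. Without both labelled mutant arrays it was 522, 507 shared. For rnt1ts at 26 C (73), the 25th percentile filter gave 115, the batch term 148 and leaving out an array 0 to 73. Without both labelled mutant arrays it was 64.

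For the change of the rnt1d effect (6), pseudocount 1 gave 13, pseudocount 64 gave 15, the deposited scale 11, the 25th and 50th percentile filters 47 and 38 (30 and 25 higher), the batch term 124 (62 higher) and leaving out an array 0 to 11. For rnt1ts (23), pseudocount 1 gave 38, the filters 74 and 77 (30 and 39 higher), the batch term 110 (50 higher) and leaving out an array 0 to 23. The temperature count stayed at 0 under every alternative run. The replicate block was fitted only for rnt1d against wild type at 26 C.

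Of lists in rnt1d at 26 C (16), an estimated correlation left 0 and fry 12, and the block and the batch term gave 17 each, adding the host genes of intronic snoRNAs. The block changed no other list's call. Some called lists had estimated correlations under the preset 0.01, such as polycistronic snoRNAs (0.0063) and a-specific genes (-0.035). Their lost calls therefore do not show correlated members. Others, such as the phosphate regulon (0.59), lay above the preset value. The few residual degrees of freedom used with an estimated correlation can end their calls too, so the cause of those losses stays open. Of temperature lists (9), an estimated correlation and fry left 0.

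Same-sign shares moved to 72.6% with pseudocount 1, 96.6% with 64 and 85.8% on the deposited scale for rnt1ts at 26 C (93.6%, 89.7 to 94.1 leaving out an array). For the array labelled rnt1d at 37 C the deposited scale gave 90% (79.8%, 79.5 to 97.6 leaving out an array). For the array labelled rnt1ts median scaling gave 95.7% and the filters 93.6% and 94.9% (97.6%, 97.2 to 100 leaving out an array). Counts at least 2-fold at 37 C became 1391, 1767 and 1580 with pseudocount 1 and 351, 307 and 264 with 64, for labelled rnt1d and labelled rnt1ts over wild type and for labelled rnt1ts over labelled rnt1d. On the deposited scale their splits were 199 higher and 344 lower, 235 and 471, and 175 and 336.

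Medians that changed sign in rnt1d at 26 C were, on the deposited scale, nuclear RNA processing 0.13, auxotrophic markers 0.15, cell cycle 0.16 and DNA damage 0.23, with the 50th percentile filter alpha-specific genes 0.33, and leaving out an array auxotrophic markers 0.010 (range -0.16 to 0.010) and DNA damage 0.021 and 0.081 (range -0.18 to 0.081). SNR39, rnt1d against wild type at 26 C, was -0.084 without rnt1d 26 C replicate 1 (range -0.084 to 0.63) and -0.077 in the additive model, and STE3 0.15 there. At 37 C against 26 C these were cell wall -0.045 with median scaling, polycistronic snoRNAs -0.058 without either rnt1ts array (range -0.058 to 0.73 leaving out an array), and other box C/D snoRNAs -0.037 without both labelled mutant arrays.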

Other observations

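The tests of genes next to snoRNAs were set before their result was seen. The count of other splits was set after the real count was known.

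Genes that follow a snoRNA on the same strand were examined in rnt1d at 26 C, under the hypothesis that unprocessed snoRNA transcripts read through into the next gene. For 17 genes after box C/D snoRNAs the median log2 change was -0.054, at the 43.1 percentile of 10000 random lists matched on mean signal, 95% of which lay between -0.26 and 0.20. Only PMD1, next to SNR52, was called, higher by 1.41 (SE 0.20, adjusted p = 0.0243), and it was chosen after its value was seen. For 9 genes after box H/ACA snoRNAs the median was -0.23, at the 12.2 percentile, and 0 were called. Neither median lay above its random lists, which argues against read-through large enough to raise these genes as a set. The next gene was taken at any distance and whether or not its snoRNA had changed. The 41 listed box C/D snoRNAs gave only 17 genes, each counted once. Read-through from single snoRNA genes is therefore not excluded.

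For 37 C against 26 C, all 54 splits of the 8 arrays into 3 and 5 that could be fitted gave at least the real count of 0, which a count of 0 makes certain, so chance is not excluded. The highest other split gave 309 called probe sets. It set both rnt1d arrays at 26 C and the array labelled rnt1ts at 37 C against the rest, which points to a structure of the samples other than temperature.

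Directly between the mutants at 26 C, a contrast added after the data had been seen, 146 probe sets differed, 75 higher and 71 lower in rnt1d than in rnt1ts (limma, 1528 at an unadjusted p under 0.05). Of the iron regulon's 27 measured genes 7 were higher in rnt1d and 0 lower, with a median of 0.94 (camera, adjusted p = 4.38e-15, and adjusted p = 0.178 with an estimated correlation). Of the 28 respiratory chain genes 7 were lower and 0 higher, with a median of -0.995 (adjusted p = 1.55e-14, and adjusted p = 0.181 with an estimated correlation). Of the 17 polycistronic snoRNAs 8 were higher and 0 lower in rnt1d, with a median of 1.47 (adjusted p = 2.06e-17, and adjusted p = 0.153 with an estimated correlation). Mating-type markers differed too, with 5 of 7 a-specific genes higher and 4 of 4 alpha-specific genes lower in rnt1d.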
